A study of Mus musculus with 3 samples.

How the data were processed

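Total RNA of pooled neural retinas from Rp1 knockout mice was measured on 3 Affymetrix MG-U74Av2 arrays, 1 array per pool. Per the labels, each pool held the retinas of 3 to 4 mice of a mixed 129/SvEv and C57BL/6 background, aged 14 days after birth, and collection took place between 1 and 2 pm. All 3 arrays form 1 group. No control genotype or other age is analysed here, so 0 comparisons between conditions were made, and the measurements are signal levels and their spread between the pools. The labels describe separate pooled RNA samples and say nothing more about how the pools relate to each other. The spread therefore holds biological and technical parts together, and the p-values measure only the spread between these samples.

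The deposited values are probe set intensity values on a linear scale, 1 per probe set and array. The software and the scaling used to make them are not given in the sources used here, and no detection calls were used. The mean after dropping 2% of probe sets at each end was 500.3 on each of the 3 arrays. By a rule fixed before the data were examined, trimmed means that differ by less than 5% count as already scaled, so the intensities were used as deposited. Values under a floor of 16 were set to 16 and log2 was taken. The floor applied to 613, 578 and 1015 probe sets on arrays 1, 2 and 3, which is 4.91%, 4.63% and 8.13% of each array.

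The table held 12488 probe sets. The 66 Affymetrix control probe sets were left out, and 12422 were analysed. Genes were named through the platform annotation given with the series, with symbols checked by gene identifier against a RefSeq table. Of the identifiers, 99.9% matched and 0 symbols changed. Of the analysed probe sets, 10833 had 1 gene symbol, 396 had several and 1193 were unnamed here; no gene was named from a probe set with several. Where a gene had several probe sets, the brightest was used. Those ending in f, r, i or g before the final part of the identifier served only where no other measured the gene. Of these, probe sets of suffix f can bind related transcripts. Probe sets of suffix s were not held back, and Pkm, Gap43, Csnk1d, Alas2 and Bfsp1 were read from such probe sets. Levels used this choice of probe set over all probe sets, and the list shifts used it among probe sets above the median signal. This gave 8251 genes. No probe set was paired with Rp1, so the targeted transcript is not analysed here and gives no check of the genotype labels.

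Spread was computed over the probe sets in the upper 50% by mean log2 signal over all 3 arrays, which lies above a signal of 224. Probe sets varying more than others of like signal were sought with limma 3.58.1 (statmod 1.5.0) in R 4.3.3. Each variance, on 2 residual degrees of freedom, was compared with an F distribution fitted robustly with the mean signal as trend. The upper-tail p was adjusted by Benjamini-Hochberg over 6211 probe sets, with a threshold of 0.05. On data simulated for these 6211 probe sets this test made 0 calls with no change. In 1 further simulated set, 1 array was shifted by 1, 2, 3 or 4 log2 units, each in 50 probe sets, all at once. The test recovered 0% of them at a shift of 1 log2 unit, 54% at 2 and 100% at 3 and at 4. There was 1 false call in the whole set. The simulated values followed the distribution that the test itself fitted, with probe sets varying independently. Few false calls were thus built in, and the simulations do not show how often real pools would give them. The large shifts ease the adjusted threshold for the others, so the recovery at 2 log2 units depends on this mix. Changes of about 2-fold are therefore below what this test can call with 3 arrays, whose number limits the precision of every value.

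The 30 gene lists of cell types and processes were fixed before the data were examined. For each list with at least 3 members above the median, the mean deviation of its members from their own 3-array mean was taken on each array. The SD of these means was placed among those of 10000 random lists of the same size matched in 20 bins of signal. A percentile above 95 was called standing apart; it describes these arrays and carries no p-value. Restricting this to probe sets above the median was implied by alternatives set in advance and was not spelled out in the test itself. In a simulation with 6211 probe sets, lists shifted on 1 array by 0.2, 0.5 and 1 log2 units reached percentiles of 97.7, 100 and 100, and 0 of 28 unshifted lists passed 95. The simulated probe sets varied independently, so this does not show how often lists of genes that vary together would pass.

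A background limit per array was chosen after the data were seen, as the highest of 15 bacterial control probe sets that looked unspiked. It was 264, 195 and 123 on arrays 1, 2 and 3. Where the dimmest array of a probe set lay under its limit, the fold was computed against that limit and is given as a lower bound. Named genes followed a fixed rule. It took the 3 brightest members of each retinal list and the brightest of each other list, the above-median member of largest SD in each list, every measured gene of the sex list, and the 20 probe sets of largest spread. As 11 named probe sets passed the hypervariability test, the next by F filled that last part. Genes named outside the rule were chosen after their values were seen.

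Alternatives planned in advance were quantile normalization, median centring, cyclic loess, floors of 1 and 64, each array left out in turn, no filter on signal, the top 25% of signal, and changes to the trend, to the probe sets entering and to the list summary. Leaving out the lens, blood, pigment and sex genes was added after seeing the data.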

Results

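The data describe the retina of Rp1 knockout mice at 14 days after birth, when photoreceptor outer segments are forming. Rp1 encodes a microtubule-associated protein of the photoreceptor outer segment, and its probe sets are not analysed here. Each of the 3 arrays carried 1 pool of retinas. Median signals were 239, 241 and 222 on arrays 1, 2 and 3, and 5878, 6984 and 7838 probe sets lay above the background limit of their array. Signals of different genes depend on their probes, so a level below says where a probe set lies on the array and is not a ranking of transcript abundance.

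Rod phototransduction transcripts gave some of the brightest signals of the array. Of 13 measured members, 12 lay above the median of all probe sets and 11 in the top 10% of genes. Gnat1, the rod transducin alpha subunit, had a signal of 38639.8 ± 6318 (SD, n = 3), Sag, rod arrestin, 34935 ± 1325, and Pde6g, the inhibitory subunit of the rod phosphodiesterase, 29200.1 ± 2223. Guca1a, a guanylate cyclase activator, had the largest spread of the list, with 3425, 5906 and 7115 on arrays 1 to 3; it did not pass the limma-based hypervariability test (adjusted p = 0.527). The list's mean deviation stayed within 0.02 log2 units on each array, at percentile 3.3 of matched random lists. With median centring it reached 0.08 (percentile 26.3) and with cyclic loess -0.05 (percentile 33.6), both on array 3.

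Cone, outer segment and regulatory genes were measured alongside. Of 8 cone genes, 5 lay above the median and 4 in the top 10%. The brightest were Gnb3, a transducin beta subunit of cones and ON bipolar cells, at 3925 ± 409 (SD, n = 3), the short-wavelength opsin Opn1sw at 2360.2 ± 627 and the middle-wavelength opsin Opn1mw at 2128 ± 830.3. Among outer segment and cilium genes, 12 of 13 lay above the median and 7 in the top 10%. Unc119 gave 16775 ± 1298, Tulp1 12939 ± 695 and the disc-membrane protein Prom1 12174 ± 777. The disc protein Prph2 had the largest spread, with 2031, 1534 and 3201 on arrays 1 to 3 (adjusted p = 0.712, limma). Of 11 photoreceptor transcription factors, 10 lay above the median, led by Mef2d at 6717 ± 432, the homeobox factor Crx at 6439 ± 1363 and Neurod1 at 3934 ± 638. Nrl, the rod fate factor, had a signal of 691 ± 160.

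**Figure D1:**
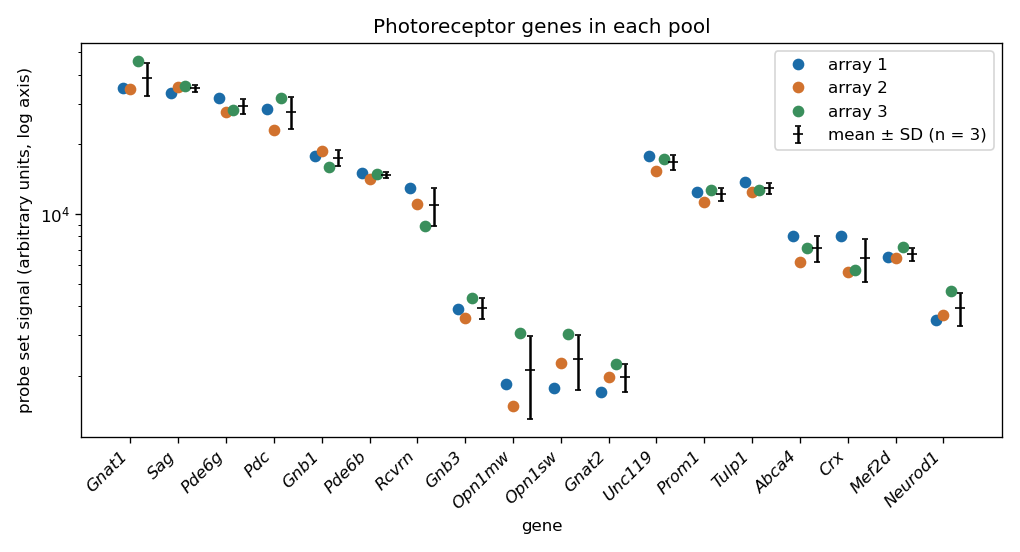
Probe set signal (arbitrary units, log axis) of photoreceptor genes on each of the 3 arrays (coloured points), with the mean ± SD beside them (n = 3). Rod genes such as Gnat1 (38639.8) and Sag (34935) lie above the cone opsins Opn1sw (2360.2) and Opn1mw (2128), and the 3 pools lie close together for most genes.

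Genes of the inner retina were measured on every array. All 7 measured bipolar genes lay above the median, with Gnao1, the G protein alpha subunit used by ON bipolar cells, at 7245 ± 1441 (SD, n = 3), Isl1 at 965 ± 138 and Car8 at 515 ± 146. Of 17 amacrine genes, 12 lay above the median, among them Calb2 (calretinin) at 7091 ± 392, the GABA-synthesis enzyme Gad1 at 4268 ± 398 and Pax6 at 2692 ± 430.3. Ganglion cell genes lay above the median in 11 of 14 cases, with Ina at 2502 ± 344, Thy1 at 2349 ± 333 and the neurofilament Nefl at 1488 ± 103. For horizontal cells it was 5 of 7, with Septin4 at 2867 ± 465, Tpm3 at 1202 ± 78.0 and Calb1 at 1129 ± 373. Within these lists the largest spreads were those of Trpm1 (187, 431 and 385 on arrays 1 to 3), the vesicular transporter Slc32a1 (1404, 2849 and 3407) and Gap43 (1348, 878 and 496), and none passed the hypervariability test. Trpm1 lay under the background limit on array 1, which leaves a range of at least 1.63-fold, so its place rests on a value under background.

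Muller glia genes were bright, with 14 of 15 above the median and 8 in the top 10%. Carbonic anhydrase 2 (Car2) gave 9759 ± 1131 (SD, n = 3), Apoe 7654 ± 993 and Rlbp1, the retinaldehyde-binding protein, 4334 ± 104. In the gliosis and injury list, 7 of 17 lay above the median and 0 in the top 10%. Its brightest members were the metallothionein Mt2 at 1245 ± 282, Stat3 at 1079 ± 48.2 and Mt1 at 939.9 ± 59.1, and Timp1 had its largest spread, at 843 ± 242. Gfap, an intermediate filament gene of reactive glia, gave 169, 102 and 44.0 on the probe set used for levels, each under the background limit of its array, and 245, 364 and 204.5 on its other probe set, above the limits of arrays 2 and 3. Microglia and immune genes lay above the median in 5 of 19 cases, with the complement gene C1qc at 568 ± 54.2 and Ctss at 452 ± 156. Without a control genotype these levels cannot be called raised or lowered.

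Genes of other cell types were measured as well. Above the median lay 12 of 17 endothelium and pericyte genes (Sparc 2477 ± 453, Acta2 262 ± 149, SD, n = 3), 2 of 9 myelin genes (Sox10 393 ± 31.4), 4 of 17 muscle genes (Pvalb, also an amacrine gene, 1666 ± 383; Mylpf 241 ± 58.5), 4 of 15 cornea and epithelium genes (Sprr1b 5431 ± 1168; Cdh1 363 ± 124) and 7 of 14 connective tissue genes (Col6a1 791 ± 70.9; Dcn 279 ± 93.0). For blood it was 3 of 7, for pigment epithelium and melanocytes 4 of 11, and for lens 8 of 12, of which 6 lay in the top 10%.

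Among process lists, glycolysis, oxidative phosphorylation and ribosomal protein had the largest shares of members in the top 10%. All 16 glycolysis genes lay above the median and 12 in the top 10%, with Pkm at 20608 ± 957 and Hk2 at 1070 ± 329.7 (SD, n = 3). Of 68 oxidative phosphorylation genes, 55 lay above the median and 39 in the top 10% (Atp5a1 8922 ± 231; Atp5pb 298 ± 89.1). Of 33 ribosomal protein genes, 22 lay above the median and 17 in the top 10% (Rpl41 29547.5 ± 2438; Rpl19 8238 ± 1759). Synaptic vesicle genes lay above the median in 19 of 20 cases, with Snap25 at 11615 ± 1272. Rab3a read 212, 151 and 765 on arrays 1 to 3, under the background limits on arrays 1 and 2, a range of at least 3.94-fold. Heat shock genes did so in 14 of 16 cases, with Hsp90aa1 at 19623 ± 2977 and Hspa1b at 650.5 ± 285.

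Stress, cell death and clock genes gave intermediate signals. In the JNK pathway list 14 of 19 lay above the median, with Jund at 7082 ± 1497 (SD, n = 3) and the phosphatase Dusp8 at 877 ± 357. Of 19 immediate early genes, 12 did, with Ier3 at 3500.3 ± 747 and Junb at 301 ± 207. Of 16 circadian genes, 13 did, with Csnk1d at 2154 ± 95.2 and Bhlhe40 at 306 ± 130.2. Apoptosis genes lay above the median in 7 of 17 cases, with Bcl2l1 at 1036 ± 189 and Bak1 at 578 ± 169, and cell cycle genes in 6 of 20, with Pcna at 1177 ± 115 and Plk1 at 413 ± 69.6.

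The pools were similar for most transcripts. Across probe sets above the median, which are not independent replicates, Pearson's r of log2 signal was 0.941 for arrays 1 and 2, 0.919 for 1 and 3 and 0.936 for 2 and 3, and Spearman's rho was 0.917, 0.894 and 0.915. The median SD over the 3 arrays was 0.24 log2 units, a factor of 1.18. A range of at least 2-fold was seen in 566 of 6211 probe sets (9.11%), of which array 1 was highest in 203, array 2 in 177 and array 3 in 186, and lowest in 203, 121 and 242. These 2-fold counts fell to 199 without array 1, 323 without array 2 and 197 without array 3, since fewer arrays give smaller ranges. The beta-actin 3' to 5' signal ratio, a measure of RNA integrity, was 1.35, 1.79 and 1.36 on arrays 1 to 3, and that of Gapdh was 0.868, 0.794 and 0.799.

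Lens crystallins, globins and Xist varied most between the pools. Of 6211 probe sets, 12 varied more than others of like signal, 7 of them of crystallins, which are structural proteins of the lens. Crygb had a signal of 12268, 16683 and 1127 on arrays 1, 2 and 3, a range of 14.8-fold (adjusted p = 0.000682, limma). Crygd read 30580.2, 41003 and 4503, and Crygc 11552, 23296 and 2765, with ranges of 9.11- and 8.43-fold. The brighter of 2 probe sets of Cryge that passed read 38210, 49193 and 5565, a range of 8.84-fold. These Crygd and Cryge probe sets can bind related transcripts. Each of the 2 genes also had a probe set without such a suffix, which lay below the median. The bright signals therefore cannot be assigned to Crygd and Cryge alone. Crygs and Crybb2 were instead far higher on array 2, at 38743 against 11102 and 12331, and at 15857 against 5178 and 3743 (adjusted p = 0.0366 and 0.0371, limma).

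The alpha-globin gene Hba-a1 was highest on array 3, at 27432 against 4540.1 and 6486, a range of 6.04-fold (adjusted p = 0.00595, limma). A probe set shared by several beta-globin genes, which also passed, read 34447 against 7945 and 10088. Xist, the RNA that coats the inactive X chromosome of females, read 3353 on array 1 and lay under the background limit on the other arrays, a range of at least 27.3-fold (adjusted p = 0.00231, limma). Prp2 and Limk1 also passed, with 657, 138 and 1218 and with 1130.1, 267 and 1672 on arrays 1 to 3. The 138 of Prp2 lay under the background limit, which leaves a range of at least 6.26-fold. The other probe sets of Prp2 and Limk1 read 212, 248 and 423, and 260.3, 241 and 276, so these calls rest on 1 probe set each. With no trend on signal limma made 0 calls, with 323 probe sets at an unadjusted p under 0.05 in the robust fit and 305 in the other. With the trend but no filter on signal it also made 0, with 338 of 12422 at an unadjusted p under 0.05. The main run had 364 of 6211. If every variance followed the fitted distribution, a share of 0.05 would lie under that p. These unadjusted counts therefore do not by themselves show varying probe sets. Without array 3 there were 13 calls, of which 4 were among the 12.

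**Figure D2:**
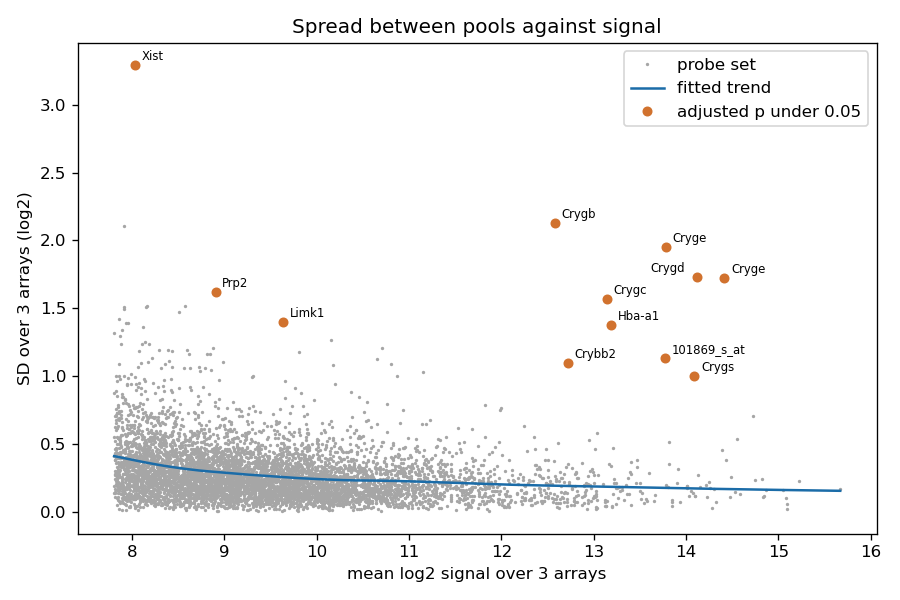
SD over the 3 arrays (log2) against mean log2 signal for the 6211 probe sets above the median (grey), with the fitted trend (line) and the 12 probe sets that passed the hypervariability test (orange). The crystallin and globin probe sets lie far above the trend at high signal, and Xist lies highest, at an SD of 3.29. That SD uses values under the background limits of arrays 2 and 3.

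Next by F, without passing, were Ptgds, Itgav, Gja1, Cant1, Pmel, Cd24a, Fbln1 and Traf5. Prostaglandin D synthase (Ptgds) read 434, 1439 and 2396 on arrays 1 to 3 on one probe set (adjusted p = 0.0501, limma), and connexin 43 (Gja1) 658, 2387 and 2682 (adjusted p = 0.0825). The melanosome gene Pmel gave 349, 1451 and 1408 (adjusted p = 0.0919), Cd24a 1302, 5090 and 1777 (adjusted p = 0.0967) and Fbln1 491, 1622 and 1949 (adjusted p = 0.106). Itgav and Traf5 were lowest on array 3 and Cant1 on array 2, with ranges from the highest to the lowest array of at least 4.80-, 5.46- and 3.74-fold. A brighter probe set of Itgav and one of Cant1 did not share this pattern, with 1396, 1822 and 2365 and with 902, 1287 and 1378.

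**Figure D3:**
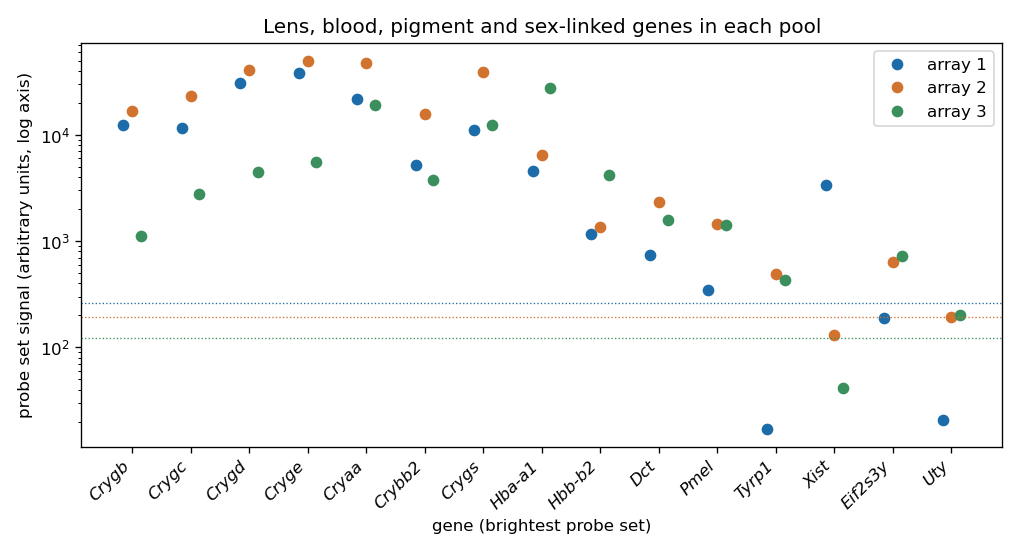
Probe set signal (arbitrary units, log axis) of lens, blood, pigment and sex-linked genes on each of the 3 arrays (coloured points), with the background limit of each array as a dotted line. The gamma-crystallins are lowest on array 3 (Crygb at 1127), Hba-a1 is highest there (27432), and Xist is above its limit on array 1 alone (3353).

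As groups, 6 of 28 lists stood apart between the pools, where 1.4 would if lists were random draws of genes. Members of a real list can vary together, so 1.4 is not the number expected from ordinary differences between pools. The 11 lens genes above the median deviated by a mean of 0.13, 1.02 and -1.14 log2 units on arrays 1, 2 and 3 (percentile 100), and all 11 had a range of at least 2-fold and were highest on array 2. Of these 11 genes, 9 were lowest on array 3, and 6 passed the hypervariability test over all probe sets against 11 adjusted over the list alone. Cryab, Crygd and Cryge entered through probe sets that can bind related transcripts, as their probe sets used for levels lay below the median. Their signals may therefore not be separate from those of other crystallins. The 3 blood genes, Hba-a1, Hbb-b2 (1166, 1354 and 4162) and the heme-synthesis enzyme Alas2 (162 and 189, under the background limits, and 537), deviated by -0.79, -0.47 and 1.26 (percentile 99.9), and 1 passed the test over all probe sets against 3 adjusted over the list alone. Without array 3 the blood percentile was 11.5, and with no filter on signal, which adds dim members, 20.6. The 4 pigment genes deviated by -0.80, 0.24 and 0.56 (percentile 100). Only 2 of them were lowest on array 1 beyond background, the melanin-synthesis enzyme Dct at 743 against 2356 and 1590.2, and Pmel; Ttr (200.5, 261 and 651.1) and Slc16a8 (204.8, 211.5 and 316.2) lay under the background limit of array 1 and show no direction between arrays 1 and 2. None of the 4 passed over all probe sets, and 3 did adjusted over the list alone. Without array 1 the pigment percentile was 53.2.

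Smaller shifts were seen in 3 further lists. The 5 cone genes above the median deviated by -0.22, -0.08 and 0.30 log2 units on arrays 1, 2 and 3 (percentile 96.4), and 4 of them were highest on array 3 (5 under each other scaling). The 14 heat shock genes deviated by 0.16, -0.03 and -0.13 (percentile 96.2). The 14 Muller glia genes deviated by -0.17, 0.09 and 0.08 (percentile 95.6), and 10 were lowest on array 1 (9 after cyclic loess), with the widest range for Glul, glutamine synthetase, at 980.1 against 2931 and 1829.9. These 3 were near the threshold: the cone list passed it under 7 of 13 alternatives, heat shock under 8 and Muller glia under 5. The floors of 1 and 64 left the shifts of these 3 lists as in the main run, so passing under them adds nothing. For the cone list the same holds for the mean over probe sets of a gene. Without the array that deviated most, the percentiles were 62.3 for cone genes, 61.2 for heat shock and 10.8 for Muller glia, and with median centring heat shock was at 61.5. Adjusted over the list alone, 1 gene passed the hypervariability test in the Muller glia list (Glul), 1 in the immediate early list (Junb: 497, 83.5, under the background limit, and 324 on arrays 1 to 3) and 0 in each of the tested lists other than these and the lens, blood and pigment lists.

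**Figure D4:**
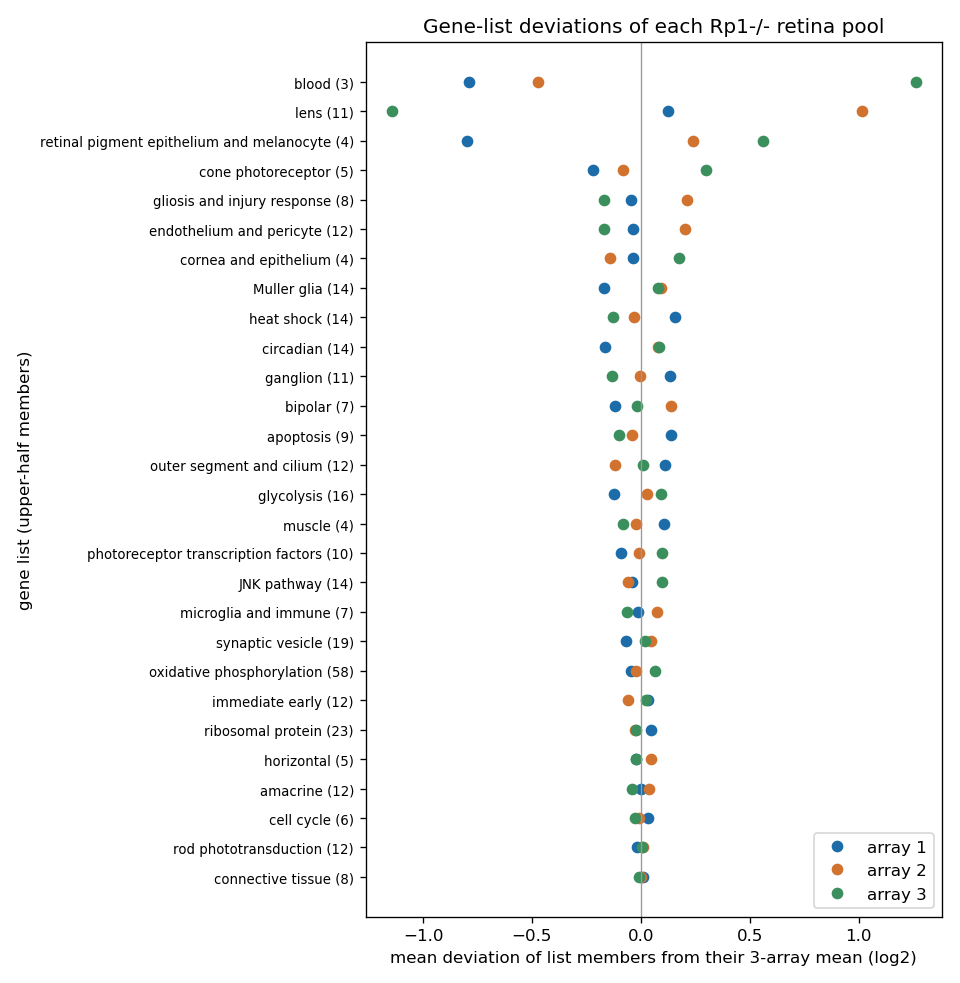
Mean deviation (log2) of each gene list's members above the median signal from their own 3-array mean, 1 coloured point per array, with lists ordered by the SD of the 3 points and the number of members in brackets. The lens (-1.14 to 1.02), blood (-0.79 to 1.26) and pigment (-0.80 to 0.56) lists spread widest, and the other lists stay within about 0.3 log2 units.

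The other 22 tested lists did not stand apart. Endothelium and pericyte (percentile 94.5), gliosis and injury (94.4), circadian (93.5) and ganglion cell genes (91.6) came nearest. Oxidative phosphorylation was at 87.1, glycolysis at 86.4, outer segment and cilium at 78.5, apoptosis at 65.6, JNK pathway and bipolar both at 63.3, cornea and epithelium at 61.6, photoreceptor transcription factors at 55.0 and synaptic vesicle at 49.1. Ribosomal protein (35.6), muscle (25.8), microglia and immune (22.5), immediate early (21.1), amacrine (18.8), horizontal (8.61), cell cycle (5.42) and connective tissue genes (0.87) came lower. Myelin and sex genes had too few members above the median to be placed.

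Of the Y-linked genes, Eif2s3y read 190.4 on array 1, under its background limit, and 631 and 718 on arrays 2 and 3, a range of at least 2.72-fold (adjusted p = 0.280, limma). Its probe set is of suffix f and can bind related transcripts. Uty read 20.6, 194.7 and 200.6, and Kdm5d 20.5, 113 and 109.9. None of these values rose above the limit of array 1, so they show no direction. Uty lay above the limits of arrays 2 (194.5) and 3 (122.7), barely so on array 2, and Kdm5d under the limit of each array. Both genes lay below the median and were not tested. Sry read 131, 73.5 and 79.0, under the background limit on each array.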

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

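The lens list stood apart under all 13 alternatives run on it, the pigment list under 10 of 11 and the blood list under 10 of 12. The floor of 1 changed none of these shifts, and the floor of 64 changed only that of the pigment list. The mean over probe sets of a gene left the blood and pigment shifts unchanged. These counts therefore hold repeats of the main run. With arrays left out in turn, the median SD was 0.17 to 0.21 log2 units, the lowest correlation 0.922 to 0.943, the count with a 2-fold range 197 to 323, the lists standing apart 3 to 7 and the highest actin ratio 1.36 to 1.79. Part of this follows from there being fewer arrays. With no filter on signal the median SD was 0.35, 4240 probe sets had a 2-fold range, 489 list members counted in place of 321, and limma made 0 hypervariable calls in place of 12 (338 at an unadjusted p under 0.05). In the top 25% of signal the SD was 0.20, the 2-fold count 136 and the lists standing apart 2. Hypervariable calls numbered 7 with median centring, which moved the arrays by -0.03, -0.04 and 0.08 log2 units, 6 without probe sets of suffix f, r, i, g or s, and 0 by limma without a trend, robust (323 unadjusted) or not (305). Without the lens, blood, pigment and sex genes, an alternative chosen after seeing the data, the count by limma was 0 (354 unadjusted), and 543 probe sets had a 2-fold range in place of 566. That alternative removed the called crystallin, globin and Xist probe sets themselves, so most of the fall in calls was fixed in advance. Prp2 and Limk1 were kept and no longer passed. A share of 0.05 of tested probe sets would have an unadjusted p under 0.05 by the fitted distribution alone. The unadjusted counts are therefore no added sign of varying probe sets. With the median over members, 3 lists stood apart. Where probe sets or genes were dropped, the loss of those that had counted is part of the change, and for the others the cause was not tested. Of 357 percentiles of single lists under the alternatives, 22 fell to or under 95 and 7 rose above it. Precision is limited by signal over background: 5878 of the probe sets of array 1 lay above its limit, against 7838 on array 3. The alternatives set out for the Rp1 signal were not run, as that transcript is not analysed here.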

Other observations

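All tests of explanations in this part were chosen after the results they bear on had been seen. All arrays belong to 1 group, so no explanation by genotype or another condition was tested, and those weighed here concern the makeup of the pools and the measurement.

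Gamma-crystallins (Crygb, Crygc, Crygd and Cryge) differed on array 3 from arrays 1 and 2 by a median of -2.97 log2 units, against -0.74 for 5 other crystallins. Compression of bright signals is argued against, since other probe sets in the top 1% of signal differed there by a median of 0.11 log2 units. Lens tissue of 1 fixed composition carried along in differing amounts would not leave the other crystallins with a lower array 1 to array 2 ratio than the gamma-crystallins; the difference in median was -0.76 (SE 0.25) with probe sets above the median, -0.97 (SE 0.45) with each gene's pick over all probe sets, and -0.64 (SE 0.38) in the version run first, which held 2 gamma-crystallins and 4 others. The verdict changed with that choice, made after the first result was seen: the first version is under 2 standard errors and the others are over. These standard errors are over genes on the same arrays and do not measure the spread between pools. In the version with probe sets above the median, Cryab, Crygd and Cryge came from probe sets that can bind related transcripts. The explanation by lens tissue of 1 fixed composition therefore stays open, and lens tissue of differing composition was not tested. Expression by the retina alone cannot be told apart from lens tissue, as only 2 lens genes other than crystallins, Bfsp1 and Mip, were above background (median -1.47).

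Globin probe sets were higher on array 3 by a median of 1.91 log2 units. More vessel tissue in that pool is argued against, as the endothelium and pericyte list differed by a mean of -0.25 (SE 0.12). This standard error is over the genes of the list and does not measure the spread between pools. Retained red blood cells are a candidate explanation that stays open, as the 4 other erythroid genes do not decide it. Alas2, set to the background limits on arrays 1 and 2, was higher on array 3 by at least 1.24 log2 units. Klf1 went the other way between arrays 1 and 3, at 295 on array 1, above its limit, and 61.9 on array 3, under its limit. Slc4a1 was above its limit on array 3 alone and Epb42 on no array.

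Xist was above background on array 1 alone. A shift of all dim signals on array 1 is argued against, since probe sets below the median differed by a median of only 0.0755 log2 units. Pools with different shares of female and male mice may account for it, but this stays open, since only 1 of 3 Y-linked genes could show a direction. Eif2s3y, set to the background limit on array 1, differed there by -1.35 log2 units, while Uty and Kdm5d did not rise above that limit on any array. Uty was above its own limits on arrays 2 and 3, barely so on array 2. Eif2s3y was read from a probe set that can bind related transcripts. The labels used here give no sex for the mice.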
